A study of Mus musculus with 10 samples.

How the data were processed

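RNA from part of the forebrain of 10 mouse embryos was hybridized to 1 Affymetrix Mouse Gene ST array per embryo, with biotin labelling of sense-strand target, per the labels' protocols. The embryos came from 2 dams, and the labels do not say which embryo came from which dam, so litter could not be modelled and may coincide in part with the groups. Groups were taken from the sample titles and annotations: 5 transgenic (dtg in the titles) and 5 control (stg) embryos. The labels do not spell out these abbreviations or say whether the controls carry a transgene. The replicate numbers were not used as pairs, because the labels do not state that they pair embryos. In 0 of 5 cases did a transgenic embryo correlate best with the control of its own number. So few cases cannot exclude pairing, and a fit with the replicate number as a block is among the alternatives.

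The deposited table holds log2 intensities for 35556 probe sets, processed by the authors with Affymetrix Expression Console, per the submitters' processing notes. The version, algorithm and settings are not stated. The near-equal medians show normalization between arrays by the authors, and no further normalization or pseudocount was applied.

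Gene names came from the platform's gene table, brought up to date through gene identifiers with the RefSeq table of GRCm38.p6, which was used only for names, chromosomes and the order of neighbouring genes. Of the probe sets, 21789 named 1 gene, 1621 several and 12146 none. Each of 19936 genes was represented by the probe set with the highest mean over all arrays; 1001 genes had more than 1. The other 13767 rows were tested separately with limma: 0 passed an adjusted p of 0.05, 732 had an unadjusted p below 0.05, and the smallest adjusted p was 0.281.

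Groups were compared with limma 3.58.1 in R 4.3.3 (linear model with group only, empirical Bayes variances, two-sided, Benjamini-Hochberg over all genes, threshold 0.05). By the unadjusted p, 1511 genes (7.58%) lay below 0.05. The median within-group SD was 0.12 on the log2 scale. Simulated data for this comparison had 200 of 19936 genes changed in each of 5 runs. The procedure recovered 96% of genes changed by 1 on the log2 scale and 78% of those changed by 0.5, with 43 false calls over all runs. The simulated noise was normal and independent between genes, and more genes were changed than the 21 called in the real data. These rates therefore need not hold for the real arrays, where genes vary together.

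The tests, the 38 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Lists with at least 4 measured genes were tested with camera at a preset correlation of 0.01, with the correlation estimated per list, and with fry. The mean log2 of each list per embryo was compared with an exact two-sided permutation test over 252 assignments, whose smallest p is 0.00794. Named genes were the FOXO family and Camk2a; in each direction up to 12 genes with the largest absolute change among those that passed, filled to 8 by smallest p; and up to 4 members with the smallest p in each list called or discussed. Clone-named genes were skipped, which left out 1 gene in each direction. Further genes named in the text were picked after their values were seen: the remaining FOXO targets, insulin-list members and Cajal-Retzius genes, Slc17a6, and the genes in the closing section.

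Alternatives were the replicate block, leaving out each embryo, trend and robust variances, array weights, quantile normalization, median centring, leaving out genes below the 40th percentile, the mean of all probe sets per gene, covariates for sex, blood and the dissection border, all probe sets, and a threshold of 0.1. Added after the data were seen were covariates for neuron content and for G2/M, the FOXO and insulin lists without shared members, and an estimated correlation without control embryo 5. Other splits of the arrays, an order test along chromosomes and Dixon's ratio within groups were also computed.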

Results

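Gene expression was measured in the forebrains of 10 mouse embryos at stage E12.5, each on its own array. In 5 transgenic embryos a permanently active form of FoxO3, a transcription factor that insulin signalling normally holds out of the nucleus, was driven by the CaMKIIa promoter, and 5 embryos served as controls. The labels do not say whether the controls carry a transgene. The question was which transcripts differ when active FoxO3 is present in the developing forebrain. The deposited values are log2 intensities, with array medians between 5.36 and 5.39, and 19936 genes could be tested. Arrays resembled each other closely, with Pearson correlations across these genes between 0.98 and 0.996. In each group 3 embryos had high Xist and low Y-linked signal and 2 had the opposite, so the sexes were balanced. The number of arrays limits the precision. The embryos came from 2 dams that the labels do not assign, so a difference between the groups could also be one between litters.

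In transgenic forebrains 13 genes rose and 8 fell at an adjusted p below 0.05 in limma, and their absolute log2 changes ran from 0.39 to 1.34. The increases with the smallest p-values were those of the stress-response gene Sesn3, at 0.72 ± 0.082 on the log2 scale (SE, n = 5 per group), and the insulin-like growth factor receptor Igf1r, at 0.50 ± 0.057. Ncapg2, which encodes a subunit of the condensin II complex, fell by 1.34 ± 0.12. Esyt2, which encodes a tether between the endoplasmic reticulum and the plasma membrane, fell by 0.77 ± 0.062. Both are among 4 neighbouring genes of chromosome 12 that fell together, taken up below. In all 21 genes every transgenic embryo lay outside the range of the 5 controls, which picking genes by p-value from these same arrays favours. Over all genes 319 showed such complete separation, 1.60% against the 0.794% that chance gives.

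Among the genes that rose, Bdh2, which encodes a dehydrogenase acting on hydroxybutyrate, had the largest change, at 1.05 ± 0.15 on the log2 scale or 2.08-fold (adjusted p = 0.0222). Pik3ip1, an inhibitor of phosphoinositide 3-kinase, rose by 0.72 (adjusted p = 0.0262), and the protein kinase gene Nuak2, a member of the AMPK-related family, rose by 0.58 (adjusted p = 0.00759). Sfrp2, a secreted modulator of Wnt signalling, rose by 0.59 (adjusted p = 0.00759), whereas the Wnt receptor gene Fzd8 fell by 0.65 (adjusted p = 0.0448). The phosphatase gene Dusp26 rose by 0.69, Hsd17b11 by 0.67, Ccdc190 by 0.60, the chromatin regulator Arid5b by 0.56, the peroxisomal transporter Abcd2 by 0.43 and the lysosomal protease gene Ctsf by 0.39. The guidance receptor gene Epha4 fell by 0.53 (adjusted p = 0.0222) and Sytl5, of the synaptotagmin-like family, fell by 0.68 (adjusted p = 0.0425). Vipr2, a receptor for vasoactive intestinal peptide, fell by 0.55 and Wdr60 fell by 0.51. Vipr2, Wdr60, Esyt2 and Ncapg2 are consecutive measured genes on chromosome 12 in the RefSeq order of GRCm38.p6, and each was measured with 1 probe set. A change of the chromosome segment that travels with a transgene is a candidate for their falls that the data could not decide. The next gene in the downward direction, Pappa2, did not pass, at -0.52 with an adjusted p of 0.0567.

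**Figure D1:**
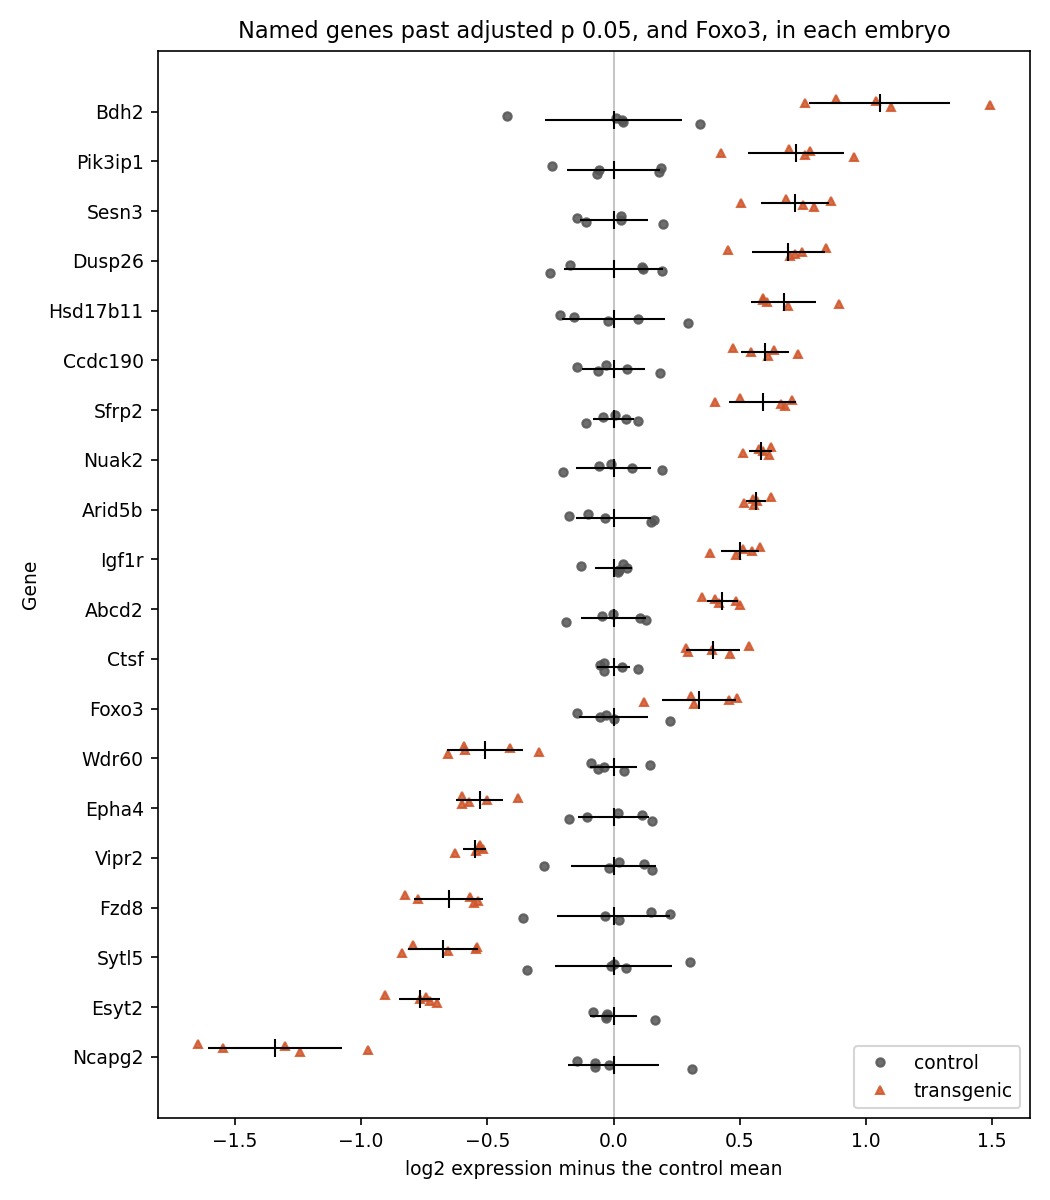
Log2 expression of the named genes past the threshold, and of Foxo3, in each of 5 control (grey circles) and 5 transgenic (orange triangles) embryos, relative to the control mean; ticks and bars show group means and SD. The groups do not overlap in any gene that passed, which picking genes by p-value from these same embryos favours, and Ncapg2 lies 1.34 lower in transgenic embryos.

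**Figure D2:**
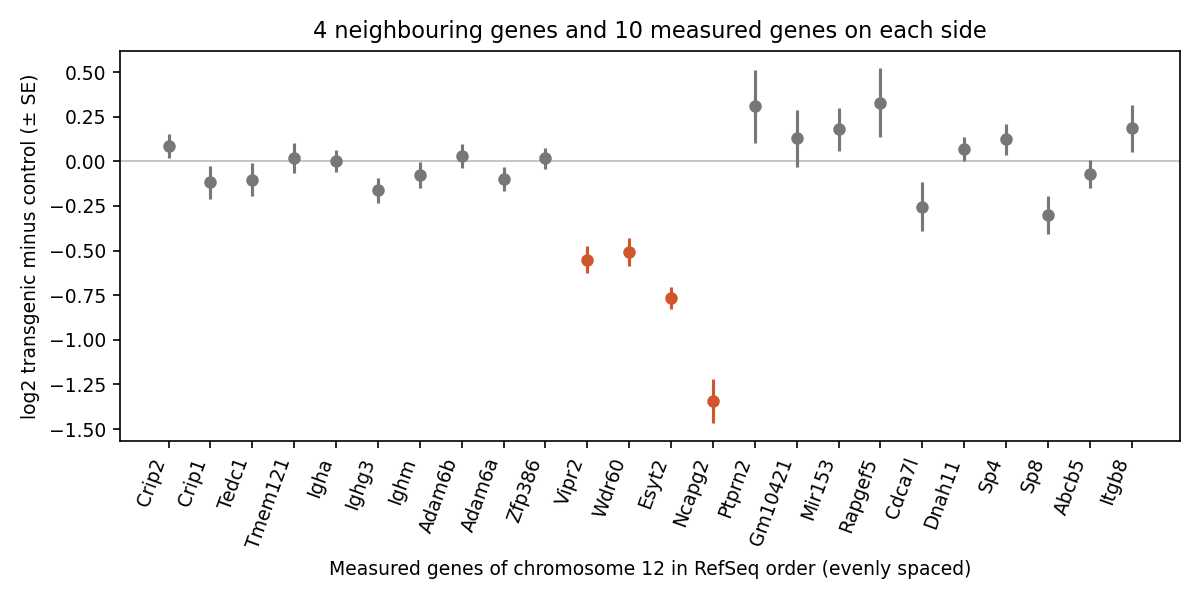
Log2 difference between transgenic and control embryos (points, with SE; n = 5 per group) for Vipr2, Wdr60, Esyt2 and Ncapg2 (orange) and 10 measured genes on each side (grey), in gene order along chromosome 12. The 4 genes lie between -1.34 and -0.51, and none of the nearest 10 passed the threshold; 4 of those have means at or below the arrays' lower quartile.

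Foxo3 itself read 0.34 ± 0.085 higher on the log2 scale in transgenic embryos, which did not pass over all genes (adjusted p = 0.218 in limma; exact permutation p = 0.0159, two-sided, n = 5 per group). The probes may not cover the transgene, so this level need not represent it. The other family members did not pass either, with log2 differences of -0.072 for Foxo1, 0.10 for Foxo4 and -0.19 for Foxo6. The Foxo1 value turned to 0.037 without control embryo 5. Camk2a, whose promoter drives the transgene, differed by -0.31 (adjusted p = 0.391).

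Known FOXO target genes were higher as a group in every transgenic embryo. Of 42 measured targets 29 were higher and 13 lower, with a mean log2 difference of 0.11 (camera adjusted p = 3.58e-07; adjusted p = 0.0069 with an estimated correlation). Sesn3 and Igf1r passed over all genes, and 8 rose when p-values were adjusted over the list alone. The further 6 were the insulin receptor substrate gene Irs2 at 0.36, Sesn1 at 0.35, the thioredoxin inhibitor Txnip at 0.52, the ubiquitin ligase gene Fbxo32 at 0.19, the mTOR inhibitor Tsc1 at 0.24 and Cited2 at 0.32. The mean log2 expression of the list was 6.90 ± 0.017 (SD) in transgenic and 6.79 ± 0.0088 in control embryos, and all 5 transgenic embryos lay above all controls (exact permutation p = 0.00794, the smallest this design allows, n = 5 per group). Targets linked to cell death and cell-cycle arrest did not pass, including Bcl2l11 at 0.073, Bbc3 at 0.059 and Cdkn1b at 0.083. The antioxidant target Sod2 also did not pass, at -0.13.

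The insulin, PI3K and mTOR list of 21 genes had a mean log2 difference of 0.074 (camera adjusted p = 0.00457; adjusted p = 0.0863 with an estimated correlation, and 0.0368 when control embryo 5 was also left out). Adjusted over the list alone, 6 members rose, among them Irs1 at 0.40 and the insulin receptor gene Insr at 0.21, and the mTOR activator Rheb fell by 0.30; Igf1r also passed over all genes. This list shares 6 members with the FOXO targets. Without these shared members its mean log2 difference was -0.0049. The autophagy and lysosome list of 22 genes had a mean difference of 0.072 (camera adjusted p = 0.0173; adjusted p = 0.473 with an estimated correlation), and no member passed over the list alone. Its smallest p-values belonged to the lysosomal protease gene Ctsd at 0.28, Map1lc3b at 0.19, Sqstm1 at 0.15 and Ulk2 at 0.17. The autophagy call was lost in 4 of the 10 fits that left out 1 embryo, while its mean stayed between 0.062 and 0.092 over all 10.

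Genes of Cajal-Retzius cells, early-born neurons at the cortical surface, were all higher in transgenic embryos. The 10 measured members had a mean log2 difference of 0.45 (camera adjusted p = 2.71e-09; adjusted p = 0.0284 with an estimated correlation). None passed over all genes, and 6 rose when adjusted over the list alone. Among them were the transcription factor gene Lhx5 at 0.98, the calcium-binding protein gene Calb2 at 0.47, Nhlh2 at 0.54 and Ndnf at 0.45. Reln at 0.21, Ebf2 at 0.22, Trp73 at 0.10 and Cacna2d2 at 0.023 did not pass over the list alone. All 5 transgenic embryos had a higher list mean than all 5 controls (exact permutation p = 0.00794). Several of these genes, Lhx5, Lhx1 and Calb2 among them, are also expressed in the diencephalon, and the thalamus list mean lay above all controls in 3 of the 5 transgenic embryos. With thalamus, hypothalamus and midbrain signal as a covariate the Cajal-Retzius mean was 0.24. The list was still called with the preset correlation (camera adjusted p = 0.000239), but that fit was not run with an estimated correlation.

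All 15 thalamus genes were higher, with a mean log2 difference of 0.72 (camera adjusted p = 1.68e-09; adjusted p = 0.286 with an estimated correlation). Adjusted over the list alone 6 rose, including Olig3 at 2.26 ± 0.51, Dbx1 at 1.11, Barhl2 at 0.95 and Lhx9 at 0.79. The exact permutation p for the thalamus list mean was 0.0397. All 23 pan-neuronal genes were higher, with a mean of 0.32 (camera adjusted p = 1.85e-06; adjusted p = 0.783 with an estimated correlation), and none passed over the list alone. Examples are Snap25 at 0.39, Nefl at 0.51, Ncam1 at 0.45 and Cntn2 at 0.26. Control embryo 5 had a pan-neuronal mean 1.17 below the other controls, and without it the mean difference was 0.088. With thalamus, hypothalamus and midbrain signal as a covariate the pan-neuronal mean turned to -0.21, called downward with the preset correlation (camera adjusted p = 0.000601). That fit was not run with an estimated correlation. The pan-neuronal genes vary closely together (estimated correlation 0.93 without the covariate), so the reversed call adds little.

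Cell-division genes had lower means in the transgenic group, by small amounts that rested mainly on embryos 1 and 3. All 23 G2/M genes were lower, with a mean log2 difference of -0.18 (camera adjusted p = 1.68e-09; adjusted p = 0.682 with an estimated correlation), as were 21 of 22 S-phase genes, with a mean of -0.15 (camera adjusted p = 9.01e-06; adjusted p = 0.783 with an estimated correlation). No member of either list passed, and the values with the smallest p were -0.24 for Kif23, -0.26 for Aurkb and -0.28 for Birc5 in G2/M, and -0.28 for Ccne2, -0.24 for Rrm2 and -0.22 for Pcna in S phase. All 17 ribosome biogenesis genes were lower, with a mean of -0.14 (camera adjusted p = 1.57e-05; adjusted p = 0.705 with an estimated correlation), for example Dkc1 at -0.28 and Npm1 at -0.22. In 3 of 5 transgenic embryos the G2/M mean lay below all controls (exact permutation p = 0.135), while transgenic embryos 2 and 4 lay within the control range. Without transgenic embryo 1 the mean difference was -0.11 for G2/M and -0.086 for S phase, and both lists were still called with the preset correlation. That setting does not allow for how closely these genes vary together (estimated correlation 0.85 for G2/M and 0.77 for S phase), so a kept call adds little.

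Of 24 radial glia genes, which mark the neural stem cells of the ventricular wall, 17 were lower and 7 higher, with a mean of -0.12 (camera adjusted p = 0.0173; adjusted p = 0.682 with an estimated correlation). Adjusted over the list alone Id4 fell by 0.33, Ddah1 fell by 0.47 and Pax6, a regulator of cortical progenitors, rose by 0.22. The radial glia call was lost without transgenic embryo 1 (adjusted p = 0.142), without transgenic embryo 3 (adjusted p = 0.063), with quantile normalization (adjusted p = 0.0837) and with an erythroid covariate (adjusted p = 0.0593). Its mean in these fits was -0.092, -0.096, -0.10 and -0.086, so the difference in them was little smaller. The radial glia difference did shrink in other fits where the call was lost. It was -0.016 with the thalamus, hypothalamus and midbrain lists as a covariate (adjusted p = 0.728). With the pan-neuronal list as a covariate it was -0.059 (adjusted p = 0.121). The glycolysis and hypoxia list of 19 genes had a mean of -0.091 (camera adjusted p = 0.0171; adjusted p = 0.783 with an estimated correlation). The oxygen sensor gene Egln3 fell by 0.41 over the list alone, and Pgk1 read -0.21. The glycolysis call was lost without control embryo 5, where the mean was -0.038 (adjusted p = 0.302), and with the pan-neuronal list as a covariate, where it was -0.021 (adjusted p = 0.584). It was also lost without transgenic embryo 1 (adjusted p = 0.0729), with array weights (adjusted p = 0.0554), without dim genes (adjusted p = 0.0852) and with an erythroid covariate (adjusted p = 0.0934). The glycolysis mean in these last fits was -0.076, -0.068, -0.077 and -0.061, so it shrank less there.

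**Figure D3:**
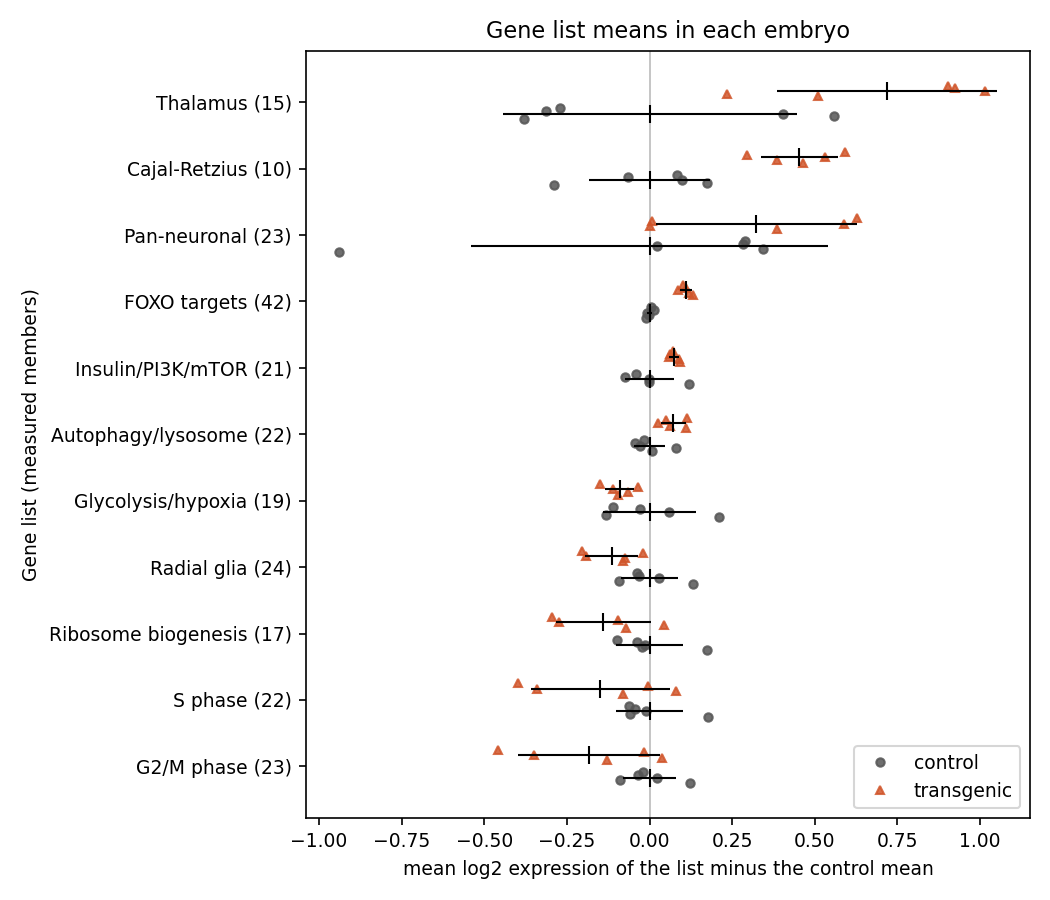
Mean log2 expression of each list past the preset-correlation test in each of 5 control (grey circles) and 5 transgenic (orange triangles) embryos, relative to the control mean, with group means and SD; the number of measured genes is in parentheses. FOXO targets and Cajal-Retzius genes separate the groups completely, while the pan-neuronal, cell-division and ribosome lists overlap.

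Several lists about neurogenesis and cell death were not called. The 15 genes of intermediate progenitors had a mean of -0.0017 with a positive median of 0.062, and camera gave an upward direction (adjusted p = 0.344). Members of that list went both ways over the list alone, with Eomes falling by 0.58 and Sstr2 by 0.60 while Rgs16 rose by 0.49 and Dll3 by 0.34. Among excitatory neuron genes, adjusted over the list alone, Neurod6 fell by 0.77 and Bcl11b fell by 0.54, whereas Nhlh2 rose by 0.54 and Slc17a6 rose by 0.53 (list adjusted p = 0.308). Among GABAergic neuron genes Foxp2 rose by 0.74, Foxp1 rose by 0.38 and Meis2 fell by 0.57 over the list alone (list adjusted p = 0.534). The G1 list held falls of 0.36 in Myc and 0.41 in Cdkn2c and a rise of 0.25 in the cell-cycle inhibitor Cdkn1c over the list alone (list adjusted p = 0.806). No Notch pathway gene passed, with Hey1 at -0.34, and no apoptosis gene passed, with Tnfrsf10b at -0.21 (list adjusted p = 0.79 and 0.57).

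Over fits that left out 1 embryo the number of genes past the threshold varied from 7 without transgenic embryo 1 to 58 without control embryo 4. It was 7 with thalamus, hypothalamus and midbrain signal as a covariate. The lists in that covariate had higher means in the transgenic group, so a lost gene call need not mean a smaller difference. Foxo3, for example, read 0.35 with it (limma adjusted p = 0.939) and 0.34 without (adjusted p = 0.218). The covariate contains the thalamus list and so cannot test it. With it the list calls were lost for G2/M (mean -0.0027), S phase (0.049), ribosome biogenesis (0.012), radial glia (-0.016) and glycolysis (0.014). The autophagy call was lost as well, though its mean of 0.059 was little smaller. Of 38 lists, 11 were called with the preset correlation, only the FOXO targets and Cajal-Retzius lists with an estimated correlation, and none by the exact test of list means after adjustment (smallest adjusted p = 0.151; 5 lists at an unadjusted p below 0.05), a test that few lists alone cannot pass in this design.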

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

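The tests of control embryo 5, of the chromosome 12 genes and of the lists against neuron content were chosen after the data were seen; only the splits of the arrays were planned. For the G2/M covariate on the chromosome 12 genes and the FOXO targets against neuron content, the expected outcomes were written after the main results but before these values were computed. Some tests were also rewritten after a first result. The spread for the tests against neuron content was added once the G2/M value had been seen; judged against a bound of 50% alone, as first written, that value would have counted against the explanation. Dilution in control embryo 5 was first judged on the radial glia list mean (0.17), with the same outcome as its median. The excitatory neuron test was added after the first test of lower maturity had come out in favour of it.

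Vipr2, Wdr60, Esyt2 and Ncapg2, neighbours on chromosome 12, were lower in 5 of 5 transgenic embryos than in any control. Chance placement is argued against: none of 10000 random sets of 21 genes held a run of 4 (permutation p = 1e-04, the smallest they can give), and the longest run was 2. Fewer dividing cells are argued against as the whole cause, since the median over the 4 genes was -0.63 with the G2/M list as a covariate and -0.66 without, although Vipr2 (-0.55, adjusted p = 0.0725) and Wdr60 (-0.42, adjusted p = 0.138) no longer passed. A change of the chromosome segment that travels with a transgene is a candidate explanation, though the labels do not say which transgenes the controls carry. The 10 measured genes around the run had a median absolute log2 difference of 0.15. Together with the falls in 5 of 5 transgenic embryos, this met the expectation written for that explanation. However, 4 of the 10 genes lie at or below the arrays' lower quartile, where the table gives no background to judge a fall by. A limit on such dim genes, not part of the written expectation, left the test over all 10 undecided. The nearest measured genes on either side are brighter and did not fall, with Zfp386 at 0.016 ± 0.059 (SE) and Ptprn2 at 0.31 ± 0.21. The fall did not extend to these neighbours, which does not by itself show its cause. Sequence variants under the probes cannot be told apart from a segment change with 1 probe set per gene. Neither an action of FoxO3 on these genes nor a difference between litters was tested.

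Control embryo 5 stood apart, with a mean correlation with the other arrays of 0.985, a pan-neuronal mean of 7.37 and an S-phase mean of 8.32. Dilution of neural RNA by other tissue is argued against as the whole cause, because radial glia genes had a median difference of 0.078 (SD 0.43) from the other 4 controls while the pan-neuronal list differed by -1.17; mesenchyme genes were nonetheless higher by 1.25. Less ventral tissue in the dissected piece may account for part, with Dlx1 at -3.83, Gad2 at -4.01 and the mean of Emx1 and Emx2 at 0.74 against the other controls. Lower maturity stays open as well: its first test came out in favour, with the pan-neuronal difference of -1.17 and S-phase, G2/M and radial glia lists above all other controls, but excitatory neuron genes, with a median of -0.079 (SD 0.42) and a list mean of -0.14 that was below all other controls, fell far less than the pan-neuronal list, and among radial glia genes Sox2 (-0.20), Hes5 (-0.26) and Fabp7 (-0.48) were lower while the dorsal genes Emx1, Emx2 and Lhx2 were higher. No biological explanation in the design separates this embryo.

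The list calls were weighed against chance and against neuron content. The 10 arrays were split into 5 and 5 in 100 ways, the real one included. Of these, 53 called as many lists as the real split (11, highest other 22). Chance is therefore not excluded for the number of lists, and the arrays hold structure beyond the groups. Only 1, the real split, gave as many genes (21, highest other 1). This argues against chance for the number of genes, though 1 of 100 is the smallest share these splits can give. The splits cannot tell an effect of the transgene from a difference between litters. With the pan-neuronal list as a covariate the FOXO target difference kept 99.4% (jackknife SE 2.78) and the thalamus difference 82.3% (SE 24.8). This argues against neuron content as the whole cause of either. Uneven tissue from the dissection border was not tested for the thalamus list, which is part of the border covariate. Its mean, relative to all arrays, was 0.20 in control embryo 4, above transgenic embryos 5 (0.15) and 4 (-0.12). In 3 of 5 transgenic embryos it lay above all controls. The G2/M difference kept 53.1% (SE 21.7), S phase 35.0% (SE 29.9), ribosome biogenesis 45.1% (SE 31.2) and radial glia 51.7% (SE 25.6), and the S-phase and radial glia calls were lost (adjusted p = 0.0762 and 0.121) while G2/M (adjusted p = 0.000215) and ribosome biogenesis (adjusted p = 0.0454) were still called. With these standard errors the position of single embryos between neurons and progenitors cannot be told apart from an effect of the group in these lists.

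Dixon's ratio picked out 19 values from 242 groups of 5, where chance gives about 12.1, and 11 of the 19 belong to control embryo 5. In control embryo 5 Esyt2 (7.33), Ncapg2 (8.03), Foxp1 (7.46), Cdon (6.94) and Foxo1 (6.68) lay far above the other controls, and Calb2 (5.10), Pfkp (5.90) and Snap25 (6.14) far below. Igf1r was low in control embryo 2, at 8.46. In transgenic embryos, Vipr2 was low in embryo 5 (4.64), Lhx5 low in embryo 2 (6.53) and Sqstm1 low in embryo 4 (8.46). Among list means, intermediate progenitors were high in transgenic embryo 5 (7.54), the Wnt list high in transgenic embryo 2 (7.18), p53 targets low in transgenic embryo 3 (6.18) and the interferon list high in transgenic embryo 3 (4.92).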

How the results depend on the processing

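The covariates for neuron content and G2/M were chosen after the data were seen. The 21 genes changed were 19 with quantile normalization, 20 with median centring and 24 with trend and robust variances. The count was 39 with array weights, 85 with the erythroid list as a covariate, 96 with the pan-neuronal list as a covariate, 9 with all probe sets (a different number tested) and 55 at an adjusted p below 0.1; with array weights and both of these covariates it held all 21. It was 7 with the thalamus, hypothalamus and midbrain lists as a covariate, 5 of them shared. Those lists had higher means in the transgenic group, so a lost call need not mean a smaller difference. The count lay between 7 and 58 over fits without 1 embryo (37 without control embryo 5). Esyt2, Ncapg2, Igf1r, Sesn3, Ccdc190, Sfrp2 and Nuak2 passed in 10 of 10 such fits, Fzd8, Sytl5 and Ctsf in 1. With the G2/M list as a covariate 10 of the 19 named genes past the threshold kept their call and none reversed. With the replicate block 2 genes passed, both lower and both among the 21.

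The 11 lists shifted were 19 with the border covariate (4 shared, of which the pan-neuronal list turned from 0.32 to -0.21; the thalamus list is part of this covariate), 2 with an estimated correlation, 3 with fry, and between 9 and 17 over fits without 1 embryo, the highest without control embryo 5. Foxo3 stayed between 0.30 and 0.39 over those fits and did not pass in any. No list mean passed the adjusted exact test as reported, with the mean of all probe sets, with quantile normalization or without 1 embryo; it was not run in other settings, and with a smallest p of 0.00794 as reported few lists alone cannot pass it, so this says nothing about stability. With the erythroid covariate the pan-neuronal mean was 0.17 and the S-phase mean -0.090. With the border covariate Pfkp turned to -0.076, Snap25 to -0.061, Cntn2 to -0.10, Nefl to -0.15, Ncam1 to -0.12, Wdr43 to 0.020 and Foxo1 to 0.16. Foxo1 was also 0.058 with the pan-neuronal and 0.044 with the G2/M covariate, and ranged from -0.11 to 0.037 without 1 embryo. None of these genes passed in the fit reported, and the cause of these changes was not tested, beyond the fewer embryos of the fits without 1. The pseudocount alternative was not run, since the values are log2. The table holds no background level per probe set, so what dim signal hides could not be judged.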

Other observations

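The genes in this part outside the fixed rule were picked after their values were seen. Of 21 neurotrophin and guidance genes 10 were higher and 11 lower, and adjusted over the list alone 6 fell and 1 rose, with Epha5 falling by 0.56, Sema3a by 0.41 and Sema3c by 0.64, and Slit2 rising by 0.30. The list itself was not called (camera adjusted p = 0.0889; adjusted p = 0.814 with an estimated correlation). In the Wnt list Wnt7a fell by 0.59 over the list alone, beside Fzd8 and Sfrp2, while the list as a whole was not called with all embryos (adjusted p = 0.58). Among immediate early genes Jun fell by 0.49 and Ccn1 by 0.43 over the list alone (list adjusted p = 0.0911).

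Single genes of lists near the dissection border passed over their lists alone, though not over all genes: Nkx2-2 rose by 0.79 in the hypothalamus list and Otx2 rose by 0.87 in the hem and choroid plexus list, and neither list was called (adjusted p = 0.444 and 0.497). Other tissues showed no called shift, with mean log2 differences of -0.12 for erythroid, -0.047 for mesenchyme, -0.040 for endothelium and 0.033 for microglia genes. Without control embryo 5, however, the mesenchyme list was called upward with a mean of 0.20 and the GABAergic list downward with a mean of -0.24. That fit also called the microglia, hem and choroid plexus, and Wnt lists upward (camera adjusted p = 0.0033, 0.0032 and 0.038). It called the neurotrophin and guidance list and the immediate early list downward (camera adjusted p = 0.00055 and 0.039). With an estimated correlation none of these lists was called (adjusted p = 0.633 for mesenchyme and 0.725 for GABAergic). Outside the lists, genes that passed only at an adjusted p of 0.1 included the netrin receptor gene Unc5c at 0.94, the polarity gene Crb1 at 0.86, the protease gene Pappa at 0.82, the cholesterol transporter gene Abca1 at 0.39, Rlbp1 at -0.81 and Dbi at -0.52.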
